A study of Mus musculus with 6 samples.

How the data were processed

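The data are bulk RNA-seq libraries of antral gastric mucosa from mice, 3 wild type and 3 with both copies of Muc6 disrupted. Per the labels' protocols, RNA was extracted with a Nucleospin RNA kit and libraries were made with a TruSeq Stranded mRNA kit, which selects polyadenylated transcripts and marks the strand. The authors deposited a table of estimated counts per gene, with a column for each library. That the values are estimated counts was taken from the values, since 28.8% to 34.25% of the values above 0 in a library are not whole, column totals differ and none is below 0. Per the submitters' processing notes the genome build was mm10. The aligner, the counting program and the annotation are not given in the sources used here, nor whether counting used the strand, so genes that overlap or have close copies may share reads. A read shared between copies can be split by such a program, which leaves the levels of near-identical genes uncertain.

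The estimated counts were rounded to whole numbers. Libraries were grouped by the genotype in the labels. Nothing in the labels states that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Libraries of a genotype differed by far more than counting noise (chi-square per degree of freedom 17.3 to 86.7), so none was counted as a repeat of another. Of 34866 gene identifiers, 34582 were matched to a symbol and coordinates in GENCODE release M21, which is on the same build, and 284 were not, at 0.043% to 0.0598% of counts. In all libraries together 13358 genes had no counts. Xist, listed among the sex-linked genes, was not analysed here. Total counts of 19839799 to 21354029 per library differed little between genotypes, so the precision of a gene depends on its level: 1 count is worth about 0.05 CPM, and differences between genes with few counts are uncertain. Where a group held no counts, the floor was 3 counts over the group, 0.0562 CPM in wild type and 0.0425 CPM in the knockout, and a fold is given as a lower bound. Where a group held 1 to 3 counts, the ratio of summed counts is given with a 95% interval.

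Genes were kept with filterByExpr in edgeR 4.0.16, which left 14017, libraries were scaled with TMM factors, and the knockout was compared with the wild type with robust quasi-likelihood fits and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. CPM values are counts per 1e6 of the TMM-scaled library size. The common coefficient of biological variation was 0.283. The gene lists cover gastric, intestinal and immune cell types, stroma, Golgi and ER stress, glycosylation, ERK targets, proliferation, stem cell and metaplasia genes, genes next to Muc6 and signs of RNA quality. There were 34 lists, fixed by name with the main test, the rule for named genes and the settings called planned in the closing section before the data were examined, and 32 of them had at least 5 tested members. These were tested on log2 CPM with camera in limma 3.58.1, with a preset correlation between genes of 0.01, and again with the correlation estimated from the data, and with fry. Adjusted p values of lists are over these 32 lists. Of these, camera called 22 and none with an estimated correlation, where 3 had an unadjusted p under 0.05. Each list's genes were also adjusted over the list alone. Medians of lists did not change when members with no counts in a group were set at their bound.

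Genes are named by a rule. Muc6 comes first, then the 12 largest changes in each direction among genes past the threshold, with non-overlapping values in the groups, a mean of at least 1 CPM and a symbol that is not a clone, Gm, Rik, LOC or pseudogene name, and then up to 4 members of each list with the smallest adjusted p among those past the threshold, or up to 2 with the smallest p where none passed. This named 138 genes, of which 1 is not reported here. A few other genes are named with values where a pattern concerns them, and these were chosen after their values were seen (Cdh17, Sis, Mep1b, Muc2, Tff3 and those of the observations on other genes).

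Alternatives were other scaling factors (RLE, upper quartile, and leaving the 20 most abundant genes out of library sizes), no filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, stricter or looser thresholds and each library left out in turn. After the data were seen, 3 were added: total counts with no composition factor, both libraries numbered 1 left out, and the trend of each library's log2 CPM over transcript GC content removed by an offset. GC content was that of the longest transcript of each gene, and 13988 of the tested genes had one. Separated groups are counted for genes whose libraries do not overlap. An exact permutation of 3 against 3 libraries cannot go below a p of 0.1. Intestinal and epithelial lists were added after the fixed ones for the tests in the closing section. Analyses used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

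The test was run on simulated data, in which counts for 13791 genes were drawn from these libraries' means, sizes and spread, and 200 genes were changed by known factors in each of 10 simulations. Of genes raised 2-fold and 4-fold, 41.2% and 75.4% were called, and of genes lowered to 0.5 and 0.25 of their level, 30.2% and 69.3%, with 0 calls of the wrong sign. False calls were 9.3% of all calls, above the nominal 5% given by the threshold of 0.05. With GC trends like those of these libraries added, 37% of calls were false with the trends left in and 7.4% with them removed. Such shares depend on how many genes change, here 200 per simulation, so they do not carry over to the 5386 genes called below. Among simulated lists of 20 genes, the list raised by a factor of 1.5 was called, and 0 of 30 unchanged lists were. Simulated genes were drawn independently, so this does not show how often unchanged lists are called when their genes move together. In these libraries the correlation estimated within a list reached 0.925 (mitochondrial mRNA).

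Values are rounded to 2 decimals on the log2 scale and to 3 significant digits otherwise.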

Results

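RNA was sequenced from the mucosa of the gastric antrum, the distal part of the stomach, of wild-type mice and of mice without Muc6, the gel-forming mucin of the antral glands. Each genotype had 3 libraries, called wild type 1 to 3 and knockout 1 to 3 below, made from polyadenylated RNA with a strand-specific kit. The series asks how loss of Muc6 relates to gastric carcinogenesis, and its title names glycosylation and Golgi stress. Total estimated counts per library ranged from 19839799 to 21354029. Levels are given as CPM, counts relative to the composition-scaled library size, as mean ± SD over the 3 libraries of a genotype (n = 3 each), and changes are log2 fold changes of knockout over wild type with their standard error (SE). The first principal component held 64.4% of the variance and separated the genotypes. The second held 19.6% and set wild type 1 and knockout 1, at 62.6 and 43.3, apart from the other 4 libraries, which lay between -43.7 and -18.8. The 3 knockout libraries expressed the Y-linked genes Ddx3y (40.5 ± 1.06 CPM) and Eif2s3y (51.1 ± 3.65 CPM), while the 3 wild-type libraries held 0.165 ± 0.142 and 0.235 ± 0.408 CPM. Sex therefore coincided with genotype in all 6 libraries, and each difference reported here is one between both.

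Muc6 transcripts were nearly absent from the knockout libraries. The gene (ENSMUSG00000048191.15, minus strand of chromosome 7, 141633456 to 141655319, mm10) was at 396, 403 and 510 CPM in wild type 1, 2 and 3, and at 0.0425, 0 and 0 CPM in knockout 1, 2 and 3. Over each genotype this was 23248 counts against 1 count, a ratio of 30700 with a 95% interval of 5510 to 1210000 (edgeR adjusted p = 7.3e-06). Intervals and floors cover counting error only.

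Of 14017 genes tested, 5386 changed between the genotypes at a false discovery rate of 0.05, with 2699 higher and 2687 lower in the knockout. Of these, 2226 differed at least by a factor of 2. The counts of the gene lists below are to be read against this background, since a random list of tested genes would hold changed genes in about that share. Scaling to total counts moved the median of all genes by 0.417 on the log2 scale and gave 5730 higher and 1091 lower, a share of 84% higher against 50.1%. All directions below are relative to the composition-scaled median. The share of the most abundant transcripts also differed: the 20 most abundant genes took 29.39% to 31.55% of counts in wild type and 19.5% to 19.8% in the knockout. How much of the shift this accounts for was not tested. The 3 values of each genotype did not overlap for 54.8% of all tested genes, where chance gives 10%. Leaving out wild type 2 gave 3342 changed genes, 1600 higher and 1742 lower, and leaving out knockout 2 gave 3531, with 1721 lower.

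The genes with the largest rises included antibody genes, secreted proteins and intestinal enzymes. The antibody light chain gene Igkc had 2 counts in wild type and 157 ± 76.6 CPM in the knockout, a ratio of 4170 (95% interval 1150 to 34500), and Iglv1, another light chain gene, was at least 188-fold higher against the floor of 3 counts over the group. The heavy chain gene Igha rose by 10.61 (SE 1.04). Gp2, which encodes a membrane glycoprotein that binds bacteria, had a ratio of 1970 (673 to 9550). Scgb2b20, a secretoglobin, was at least 254-fold higher, and both Prss22, a serine protease, and Adgrg7, an adhesion receptor, were at least 190-fold higher. The matrix protease gene Mmp10 rose by 10.07 (SE 0.47), from 0.111 ± 0.113 to 127 ± 31.3 CPM, and Chil4, a chitinase-like protein gene, rose by 10.55 (SE 1.61) to 3106 ± 2304 CPM. Ltf (lactoferrin), Akp3 (an alkaline phosphatase of the intestine) and Sult6b2 (a sulfotransferase) rose by 10.98, 10.39 and 9.99, but in the knockout each was carried mainly by some libraries, with Ltf at 542, 39.9 and 20.7 CPM and Akp3 at 28, 525 and 1139 CPM. Their calls ended when single libraries were left out. For Ltf this was any 1 wild-type library (adjusted p 0.0683 to 0.102), for Akp3 wild type 2 (0.0538), for Sult6b2 any 1 wild-type library or knockout 2 (0.0569 to 0.123), and for Adgrg7 knockout 2 (0.0511). Igha and Iglv1 lost theirs without both libraries numbered 1 (0.117 and 0.132). With limma-voom the calls of Ltf, Akp3, Sult6b2, Adgrg7 and Scgb2b20 ended (0.0526 to 0.518), and with no low-count filter those of Ltf, Adgrg7 and Sult6b2 did (0.0515 to 0.0658).

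Apart from Muc6, the largest falls were in Dthd1, in parietal and chief cell genes of the gastric body, and in the gastrin gene. Dthd1 went from 11.4 ± 1.42 CPM to 2 counts, a ratio of 401 (95% interval 111 to 3320). Gast, which encodes the acid-stimulating hormone gastrin, fell by 5.99 on the log2 scale (SE 0.44), from 1041 ± 241 to 16.4 ± 7.77 CPM. The proton pump genes Atp4b (-6.67) and Atp4a (-5.81), the potassium channel subunit gene Kcne2 (-6.85) and the acidic chitinase gene Chia1 (-6.55) also fell. Further falls were in Tnni3 (cardiac troponin I, -6.07), Fabp3 (a fatty acid-binding protein, -5.79), Pnoc (prepronociceptin, -5.69), Esrrg (a nuclear receptor, -5.65) and Tmem45a2 (-5.56). Wild type 1 held less Atp4b than wild type 2 and 3, at 6.41 CPM against 143 and 140. Atp4a, Kcne2, Chia1, Tnni3, Fabp3 and Esrrg were likewise lowest in wild type 1 among the wild-type libraries. Fabp3, for example, was at 1.14 CPM against 20.8 and 16.5, and Tnni3 at 1.3 CPM against 7.2 and 9.92. The falls of these genes may therefore not be separate changes. Wild type 1 was not the lowest for Gast, Pnoc or Tmem45a2, and Dthd1 differed little among wild-type libraries. The calls of Atp4a and Atp4b ended without wild type 2, wild type 3, knockout 1 or knockout 2 (0.0535 to 0.0782 and 0.0673 to 0.0939), and that of Fabp3 without any 1 knockout library (0.057 to 0.0731). With limma-voom the calls of Atp4a, Atp4b, Fabp3, Kcne2, Chia1, Tnni3 and Esrrg ended (adjusted p 0.0697 to 0.359), and with no low-count filter those of Atp4a, Atp4b and Fabp3 did (0.0537 to 0.0702).

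**Figure D1:**
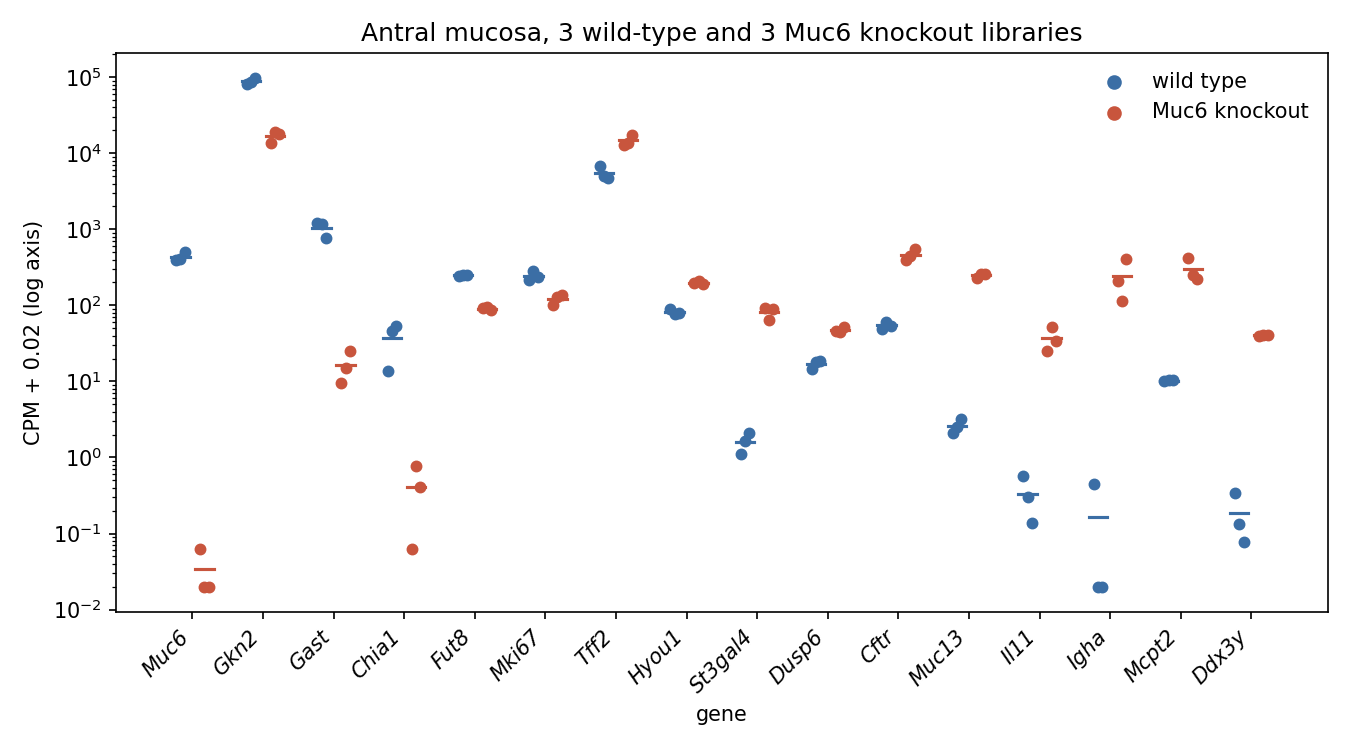
CPM (plus 0.02, log axis) of 16 named genes in the 3 wild-type and 3 Muc6 knockout libraries, with points for libraries and lines for the mean of each genotype. The libraries of the genotypes do not overlap for any gene shown. All were picked from genes past the threshold, of which 99.4% do not overlap, so this follows from the choice. Muc6 lies at 396 to 510 CPM in wild type and at 0.0425 CPM or 0 in the knockout.

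Genes of the surface (pit) mucous cells, which coat the stomach lining, fell together. Of 12 tested list members, 10 fell, none rose and 2 did not pass, and 10 also fell when adjusted over the list alone. Gkn2 and Gkn1, the gastrokines, fell by 2.37 (SE 0.20) and 2.11 (SE 0.21) on the log2 scale, Gkn2 from 88031 ± 7577 to 16994 ± 2909 CPM, and together they took 11.7% to 12.93% of counts in wild type and 2.74% to 3.85% in the knockout. Sytl2, a vesicle trafficking gene, and Capn8, a stomach calpain gene, fell by 1.48 and 1.53 on the log2 scale. The list was lower than other genes by camera (adjusted p = 1.31e-04), which was lost at adjusted p = 0.494 with an estimated correlation, and with total counts 6 members were lower and 1 higher. Among the mucous cell genes of the glands, 6 of 12 rose and 3 fell (7 and 3 adjusted over the list alone), with a camera adjusted p of 0.158. Tff2, the trefoil peptide secreted with Muc6, rose by 1.42 (SE 0.21), from 5522 ± 1181 to 14758 ± 2527 CPM, and Bpifb1, a secreted defence protein, rose by 4.50 (SE 0.47). Cd44, a hyaluronan receptor, rose by 1.27, and Smim6 fell by 0.83 on the log2 scale. The number of gland genes lower was 1 without wild type 2, wild type 3 or knockout 2. In the list of gastric body genes, 2 of 14 rose and 6 fell (2 and 7 adjusted over the list alone, camera adjusted p = 0.158), with Kcnq1 and Mfsd4a higher by 1.59 and 1.67 and Chia1 and Esrrg among those lower. Camera called this list as lower without wild type 1 (adjusted p = 0.0186), the wild-type library with the lowest median of these genes, without both libraries numbered 1 (0.0311), with total counts (0.011) and with the GC trend removed (0.0397). With limma-voom 1 member was lower.

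Of 29 tested genes of hormone (enteroendocrine) cells, 12 fell, 1 rose and 16 did not pass, with 15 and 1 adjusted over the list alone. Besides Gast, Cpe, a prohormone-processing enzyme gene, fell by 2.43 (SE 0.29) on the log2 scale, from 146 ± 19.5 to 27.0 ± 9.53 CPM, and Isl1 and Rfx6, transcription factor genes of endocrine cells, fell by 2.44 and 2.14. The list median was -1.88, and camera placed the list lower (adjusted p = 3.19e-06), which was lost at adjusted p = 0.569 with an estimated correlation. The number lower was 6 without wild type 2, 7 without wild type 3 and 19 without knockout 1, and the 1 higher member was not called without any single wild-type library, knockout 2 or knockout 3, while 2 were higher without knockout 1. Without both libraries numbered 1, 20 were lower and 2 higher. Of 15 tuft cell members, 3 rose and none fell, but none passed when adjusted over the list alone. These were Alox5ap, needed for leukotriene synthesis, Trpm5, a taste cation channel, and Spib, a transcription factor, at 1.49, 1.03 and 1.36. Camera placed the tuft list higher (adjusted p = 0.0323), lost at adjusted p = 0.577 with an estimated correlation. All 3 calls ended without wild type 2, knockout 1 or knockout 3 (adjusted p 0.0721 to 0.141), 1 member was higher without wild type 1 and 7 were without wild type 3. Without wild type 1 the call of Trpm5 (0.0835) and that of Spib (0.0712) ended, and the call of Spib ended without knockout 2 (0.0661). Without both libraries numbered 1 all 3 calls ended (0.0552 to 0.128), with the GC trend removed those of Trpm5 (0.112) and Spib (0.105) did, and with limma-voom that of Trpm5 did (0.0549). The camera call of the tuft list ended without wild type 1, wild type 2 or knockout 1 (0.0777 to 0.0886), without both libraries numbered 1 (0.158), with total counts (0.154), where 7 members were higher, and with the GC trend removed (0.352).

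Glycosylation enzyme genes rose more often than they fell. In the O-glycosylation list, which builds mucin sugar chains, 15 of 32 tested members rose and 3 fell, as also adjusted over the list alone. St3gal4, a sialyltransferase gene, rose by 5.69 (SE 0.27), from 1.6 ± 0.501 to 83.0 ± 15.7 CPM, and Galnt18, Galnt10 and Galnt3, enzymes that start O-glycans, rose by 3.02, 1.15 and 1.13. Camera placed the list higher (adjusted p = 0.0191), lost at adjusted p = 0.567 with an estimated correlation and at 0.0749 with total counts. In the N-glycan processing list, 15 of 43 rose and 3 fell, as also adjusted over the list alone. Fut8, the core fucosyltransferase gene, fell by 1.46 (SE 0.09) on the log2 scale, from 249 ± 3.65 to 90.8 ± 4.89 CPM, while Prkcsh (a glucosidase subunit), Uggt1 (a folding sensor) and Mgat4a (a branching enzyme) rose by 1.33, 0.78 and 0.77. Camera placed the list higher (adjusted p = 0.00972), lost at adjusted p = 0.567 with an estimated correlation and at 0.0832 with the GC trend of each library removed, and with total counts 30 were higher and 2 lower. The number of O-glycosylation genes higher was 8 without wild type 2 and 9 without wild type 3.

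Golgi genes moved in both directions, about as often as tested genes as a whole, of which 2699 of 14017 rose and 2687 fell. Of 23 tested members of the Golgi stress list, 5 rose and 4 fell (6 and 4 adjusted over the list alone), with a camera adjusted p of 0.137. St3gal6, a sialyltransferase gene, rose by 1.14 (SE 0.12), Hs6st1, a heparan sulfate enzyme gene, by 0.81, and Tfe3, a transcription factor of the Golgi stress response, by 0.82 (SE 0.14), from 17.3 ± 2.42 to 30.6 ± 1.73 CPM. Golph3, a Golgi membrane protein gene, fell by 0.48 on the log2 scale. In the Golgi structure and traffic list, 8 of 45 rose and 9 fell, as also adjusted over the list alone (camera adjusted p = 0.491), and the median was -0.04 but 0.38 with total counts, where 23 rose and 1 fell. Bet1 (a vesicle fusion gene), Copb1 (a coat protein gene) and Gcc2 (a golgin) fell by 0.93, 0.74 and 0.55 on the log2 scale, and Gcc1, another golgin, rose by 0.65. The calls of Golph3 and Gcc2 ended with total counts (adjusted p = 0.598 and 0.377) and with the GC trend removed (0.339 and 0.366), that of Copb1 with total counts (0.104) and that of Bet1 with the GC trend removed (0.0991). Golgi stress genes numbered 15 higher and 0 lower with total counts. Those higher and lower numbered 3 and 2 without wild type 2, and 2 were lower without wild type 3 or knockout 3 and 1 without knockout 2. Golgi structure genes numbered 3 higher and 3 lower without wild type 2 and 5 higher and 4 lower without knockout 2, and 3 were higher without wild type 3 or knockout 3 and 5 without knockout 1. With the GC trend removed they numbered 7 higher and 5 lower.

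In the list of genes of endoplasmic reticulum (ER) stress, 11 of 36 rose, 6 fell and 19 did not pass (14 and 6 higher and lower adjusted over the list alone), with a camera adjusted p of 0.0756. Hyou1 and Pdia4, folding factors, rose by 1.27 (SE 0.10) and 1.29 (SE 0.11), Hyou1 from 82.0 ± 6.95 to 197 ± 8.25 CPM, and Sdf2l1 and the calreticulin gene Calr rose by 0.97 and 0.93. With total counts 25 were higher and 3 lower. The number higher was 6 without wild type 2 or wild type 3, and 3 were lower without knockout 2. Camera called the list as higher without wild type 1 (adjusted p = 0.0316) and without both libraries numbered 1 (0.0283).

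Target genes of the ERK kinase pathway rose, with 15 of 27 higher and none lower (16 higher adjusted over the list alone). Dusp6 and Dusp4, phosphatases that act back on ERK, rose by 1.47 (SE 0.13) and 1.86 (SE 0.22), Dusp6 from 17.1 ± 2.16 to 47.2 ± 3.84 CPM, and Plaur, the urokinase receptor gene, and Phlda1 rose by 1.95 and 1.24. Camera placed the list higher (adjusted p = 3.89e-04), lost at adjusted p = 0.434 with an estimated correlation, and 9 members were higher without wild type 2 or knockout 2, while 1 was lower without knockout 3. Proliferation genes were lower in 11 of 34 and higher in none, as also adjusted over the list alone, but 10 were higher and 3 lower with total counts, where the list median of -0.20 became 0.22. Mki67, the gene of the Ki-67 antigen, fell by 0.99 (SE 0.16) on the log2 scale, from 244 ± 33.9 to 123 ± 19.6 CPM. Hmgb2, a chromatin protein gene, fell by 1.91 (SE 0.14), Nusap1, a spindle gene, by 1.13 and Tyms, a nucleotide synthesis gene, by 0.64 on the log2 scale, and the call of Tyms ended with total counts (adjusted p = 0.0961). Camera placed the proliferation list lower (adjusted p = 0.0397), lost at adjusted p = 0.641 with an estimated correlation, at 0.176 without wild type 1, at 0.143 without knockout 1 and at 0.154 with total counts, and 2 members were higher without wild type 1. Leaving out 1 library moved the proliferation median to between -0.30 (without knockout 2) and -0.07 (without knockout 1). Without both libraries numbered 1, the median was 0.01, 3 members were higher and 11 lower, and camera gave 0.497. In the Wnt and stem cell list, 6 of 23 rose and 2 fell, as also adjusted over the list alone (camera adjusted p = 0.088). Ephb3 and Ephb2, receptors for ephrins, rose by 2.05 (SE 0.17) and 2.22 (SE 0.27), and Prom1, a membrane glycoprotein gene, rose by 1.51 (SE 0.16). The number lower was 1 without wild type 2 or knockout 3, and camera called the list as higher without knockout 1 (adjusted p = 0.0204), with no low-count filter (0.0431) and without both libraries numbered 1 (0.0342), where 4 were lower. With total counts 11 were higher and 1 lower.

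Genes of spasmolytic polypeptide-expressing metaplasia (SPEM) and dysplasia, a list of markers of injured and precancerous stomach, were higher in 25 of 33 and lower in 2 (28 and 2 adjusted over the list alone). Cftr, the chloride channel gene, rose by 3.10 (SE 0.16), from 54.5 ± 6.16 to 466 ± 76.6 CPM, Cldn2, a tight junction gene, rose by 3.23 (SE 0.20), and Mmp10 rose as given above. Anxa10, an annexin gene of gastric surface cells, fell by 1.97 (SE 0.15) on the log2 scale, from 7455 ± 790 to 1909 ± 182 CPM. The list was higher by camera (adjusted p = 5.44e-08), which was lost at adjusted p = 0.0785 with an estimated correlation. Of 27 tested intestinal genes, 13 rose and 2 fell (17 and 2 adjusted over the list alone). Muc13, a transmembrane mucin gene, rose by 6.59 (SE 0.19), from 2.6 ± 0.565 to 250 ± 17.2 CPM, and the lectin and regeneration genes Reg1, Reg3b and Reg3g, which may share reads, rose by 8.78 (SE 0.52), 9.20 (SE 0.62) and 6.72 (SE 0.37). Muc13 differed little among knockout libraries (230, 262 and 257 CPM), whereas Cdh17, an intestinal cadherin gene, was at 5, 90.2 and 199 CPM in knockout 1, 2 and 3, and Sis, the sucrase gene, at 0.9, 14.5 and 27.9 CPM. Camera placed the intestinal list higher (adjusted p = 0.00241), lost at adjusted p = 0.569 with an estimated correlation and at 0.149 with total counts. Of 32 intestinal genes tested in each case, 6 were higher without wild type 2, 22 without knockout 1 and 20 without both libraries numbered 1. With DESeq2 23 of 33 were higher and 4 lower, and with limma-voom 7 of 27 were higher. None was lower without wild type 1, wild type 2 or knockout 2, with total counts or with the GC trend removed, and 1 was without wild type 3 or with no low-count filter.

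**Figure D2:**
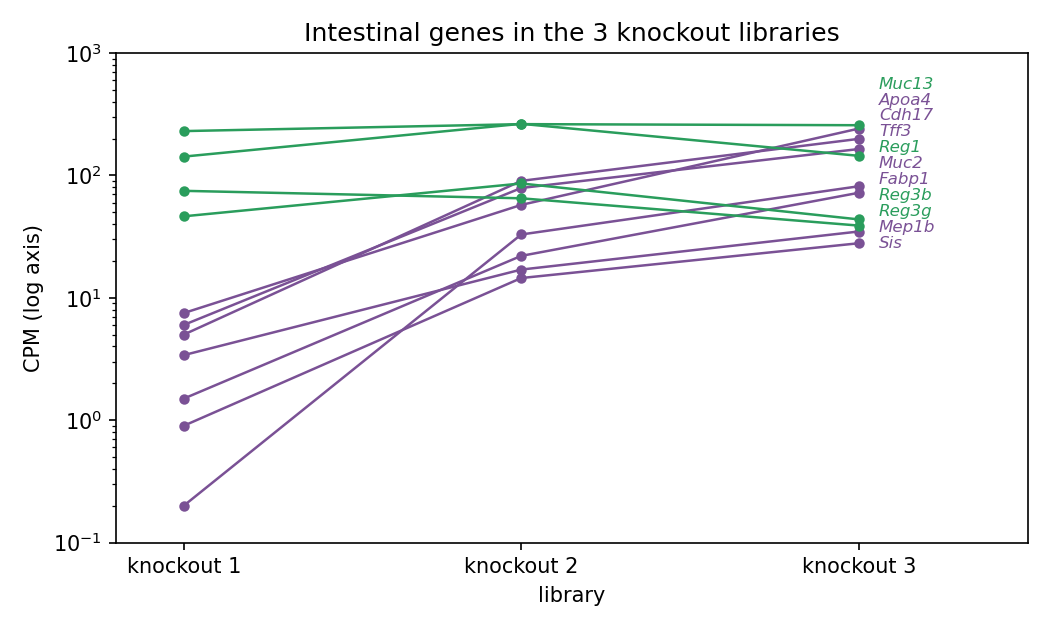
CPM (log axis) of 11 intestinal genes in knockout 1, 2 and 3, in which lines only join the values of a gene. Muc13 and the Reg genes (green) stay within 38.9 to 264 CPM in each library, while Cdh17, Muc2, Tff3 and the other genes (purple) are lowest in knockout 1 and highest in knockout 3.

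Inflammatory mediators rose in 20 of 23 tested members and fell in 1 (21 and 1 adjusted over the list alone). The low-count filter left these 23 of 35 list members. Genes nearly absent from wild type pass it only if the knockout libraries express them, so the tested members lean toward rises. With no filter, 17 of 34 were higher and 1 lower. The cytokine gene Il11 rose by 6.85 (SE 0.49), from 0.314 ± 0.215 to 37.3 ± 13.8 CPM, the chemokine gene Cxcl16 by 2.31 (SE 0.16) and the alarmin gene Il33 by 1.98 (SE 0.20). Il18, another cytokine gene, fell by 2.65 (SE 0.15) on the log2 scale, from 384 ± 29.6 to 61.2 ± 9.64 CPM. Camera placed the list higher (adjusted p = 1.85e-07), lost at adjusted p = 0.434 with an estimated correlation, and 13 members were higher without wild type 2 or with limma-voom and 12 without wild type 3. Interferon response and antigen presentation genes rose in 23 of 30 and fell in none (27 higher adjusted over the list alone). The immunoproteasome gene Psmb8 rose by 2.19 (SE 0.25), from 2.15 ± 0.127 to 9.85 ± 2.08 CPM, and the interferon-induced genes Isg15 and Oasl2 rose by 4.43 (SE 0.56) and 4.60 (SE 0.52). The list was higher by camera (adjusted p = 3.74e-08), which was lost at adjusted p = 0.434 with an estimated correlation.

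Many immune cell genes fell below the low-count filter. It left 9 of 21 B and plasma cell genes, 5 of 24 T and NK cell genes and 8 of 16 neutrophil genes. A gene nearly absent from wild type passes it only if the knockout libraries express it, so the tested members lean toward rises. With no filter, 11 of 21, 6 of 24 and 4 of 15 were higher and none lower. All 9 tested B and plasma cell genes rose, also adjusted over the list alone. Among them were Jchain, which joins antibody chains, by 8.11 (SE 0.47), from 0.245 ± 0.0942 to 69.2 ± 26.5 CPM, and Ighm by 4.06 (SE 0.73). Igh and Igk gene segments can share reads, so the values of single antibody genes are uncertain. The list was higher by camera (adjusted p = 1.7e-05), which was lost at adjusted p = 0.392 with an estimated correlation. Of 5 tested T and NK cell genes, 3 rose (4 adjusted over the list alone), with Gzmb (granzyme B) at least 17.4-fold higher, Trbc2, a T cell receptor gene, at a ratio of 51.5 (95% interval 17.4 to 252), and Cd4 higher by 3.50 (SE 0.85). Of 8 neutrophil genes, 4 rose (8 adjusted over the list alone), including Mmp9, a gelatinase gene, at a ratio of 199 (68.0 to 969), Il1r2, a decoy receptor gene, by 3.64 and Csf3r, the receptor gene for granulocyte colony-stimulating factor, by 4.57. Knockout 1 held most of the neutrophil signal, with a median deviation of 2.99 on the log2 scale from the mean of the 6 libraries against -0.15 and 0.08 in knockout 2 and 3. Mast cell and eosinophil genes were higher in 3 of 12 (9 did not pass), as also adjusted over the list alone, all of them mast cell protease genes with related sequences, Mcpt2 by 4.86 (SE 0.27), from 10.2 ± 0.171 to 298 ± 107 CPM, Mcpt1 by 7.24 and Mcpt4 by 6.43. Of 19 macrophage and dendritic cell genes, 2 rose and none passed when adjusted over the list alone, and these were Fcgr3, an antibody receptor gene, by 2.11 and Itgax, an integrin gene, by 2.27.

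Camera placed these last 4 immune lists higher, the T and NK list at an adjusted p of 0.00825 (adjusted p = 0.494 with an estimated correlation), neutrophils at 0.00407 (adjusted p = 0.569 with an estimated correlation), mast cells and eosinophils at 0.00464 (adjusted p = 0.567 with an estimated correlation) and macrophages and dendritic cells at 0.0142 (adjusted p = 0.594 with an estimated correlation). Each of these 4 camera calls ended with total counts (0.074 to 0.227), although the genes higher then numbered 4, 7, 4 and 9. The list medians were also higher there, at 3.90, 6.43, 1.96 and 2 against 3.50, 6.03, 1.54 and 1.58. Single libraries moved each of them further. The neutrophil median was 3.17 without knockout 1. Without wild type 3 the medians were 6.50 for T and NK genes, 2.10 for mast cells and eosinophils and 2.11 for macrophages and dendritic cells. Without wild type 1 the last was 1.045. The filter keeps other numbers of list members in some settings. T and NK genes numbered 5 higher of 9 tested without wild type 3 and 6 of 8 without knockout 1, and the call of Cd4 ended without wild type 2 (0.051) or knockout 3 (0.0542). Neutrophil genes higher numbered 2 without any 1 wild-type library, and the call of Csf3r ended without each of these (0.0636 to 0.0817) and without knockout 1 (0.0518). Its rise was 2.83 without knockout 1, which held 5.69 CPM against 0.623 and 0.785 in knockout 2 and 3. Macrophage genes higher numbered 8 without wild type 1, none without wild type 2 or wild type 3, and 1 without knockout 1 or knockout 2. The call of Fcgr3 ended without wild type 2, wild type 3 or knockout 1 (0.0537 to 0.0629), and that of Itgax without any single library other than wild type 1 (0.0542 to 0.0933). With limma-voom the calls of Mmp9, Csf3r, Mcpt1 and Mcpt4 ended (adjusted p 0.083 to 0.0951), and 1 neutrophil gene and 8 macrophage genes were higher. With DESeq2 10 of 22 tested macrophage genes and 6 of 16 T and NK genes were higher. These were 10 of 19, with 1 lower, and 6 of 8 without both libraries numbered 1. The call of Itgax also ended with the GC trend removed (0.0518), where 1 macrophage gene was higher.

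Endothelial genes were higher in 6 of 18 and lower in 2 (9 and 2 adjusted over the list alone). Pecam1, an adhesion molecule gene of vessel walls, rose by 1.06 (SE 0.16), from 10.8 ± 0.8 to 22.6 ± 3.86 CPM, and Vwf (von Willebrand factor), Tie1 (a receptor) and Egfl7 rose by 2.75, 2.57 and 1.28. Camera placed the list higher (adjusted p = 0.00825), lost at adjusted p = 0.577 with an estimated correlation and at 0.167 with total counts. Of 22 fibroblast genes, 1 rose and 1 fell, with none adjusted over the list alone (camera adjusted p = 0.125), Bgn (biglycan) by 2.52 (SE 0.71) and Gsn (gelsolin) lower by 0.64 on the log2 scale. None of the 20 smooth muscle genes passed, over all genes or adjusted over the list alone, and Casq2 and Sncg had adjusted p values of 0.0716 and 0.13. The muscle list had a median of -1.40 and a camera adjusted p of 0.0419, lost at adjusted p = 0.641 with an estimated correlation. Leaving out 1 library moved this median to between -2.04 (without knockout 2) and -0.69 (without wild type 3). Muscle genes varied widely within each genotype, with median deviations of -1.24, 1.24 and 2.18 on the log2 scale in wild type 1, 2 and 3 and of -2.60, 0.34 and 0.05 in knockout 1, 2 and 3. The muscle call ended without wild type 2, wild type 3 or knockout 1 (0.0802 to 0.265), and 1 muscle gene was lower without wild type 1 or with DESeq2 (Casq2, 0.00757 and 0.0131). Without both libraries numbered 1, 7 muscle genes were lower, and the list had a camera adjusted p of 2.5e-04. With the replicate number as a block, 12 muscle genes were lower, at a camera adjusted p of 3.4e-05. Endothelial genes numbered 10 higher without wild type 1, 2 higher and none lower without wild type 2, and 3 higher and none lower without knockout 2, and 1 was lower without wild type 3, knockout 1 or knockout 3. The call of Vwf ended without wild type 2 (0.0506), and that of Egfl7 without wild type 2 (0.0567) or knockout 2 (0.0646) and with the GC trend removed (0.0522). Endothelial genes numbered 10 higher with total counts or DESeq2 and 13 without both libraries numbered 1. Fibroblast genes numbered 4 higher and 6 lower without wild type 1, 4 and 7 without both libraries numbered 1 and 3 and 0 with total counts. The call of Bgn ended without wild type 2 or any 1 knockout library (0.0629 to 0.119), with no low-count filter (0.0985) and with the GC trend removed (0.0607), while that of Gsn ended without wild type 3, knockout 1 or knockout 2 (0.0507 to 0.0668) and with total counts (0.319). Camera called the fibroblast list as higher without wild type 3 (adjusted p = 0.0113), with a median of 1.37.

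Other cell types of the stomach wall and its surroundings were compared in the same way. Of 16 neuron and glia genes, 2 rose and none fell, as also adjusted over the list alone, S100b, a calcium-binding protein gene, by 2.52 (SE 0.38) and Ret, a receptor kinase gene, by 2.08 (SE 0.40), although the list median was -1.53. Camera placed this list lower (adjusted p = 0.0397), lost at adjusted p = 0.594 with an estimated correlation and at 0.0797 and 0.0742 without wild type 1 and wild type 3 and at 0.114 with a filter of 1 CPM in 3 libraries. Members lower numbered 3 without knockout 1 or with limma-voom, 1 without knockout 3, 4 without both libraries numbered 1 and 5 with DESeq2. Among keratinocyte genes of the squamous forestomach, 5 of 11 rose and none fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0705), with Ivl (involucrin) higher by 7.32 (SE 0.40), from 0.632 ± 0.246 to 102 ± 34 CPM, the keratin genes Krt4 and Krt13 higher by 4.42 and 2.96 and Krt14 at a ratio of 34.5 (95% interval 9.27 to 289). The squamous genes higher numbered 3 without wild type 2, wild type 3 or knockout 2, and those lower numbered 1 without wild type 2 or knockout 2 and 2 without knockout 1. With limma-voom 3 were higher and 1 lower, and with DESeq2 6 of 15 were higher and 2 lower. The low-count filter left 11 of 24 squamous genes, and with no filter 5 of 21 were higher and 1 lower. Camera called the squamous list as higher without wild type 1 (adjusted p = 0.0436), without both libraries numbered 1 (0.0329) and with no low-count filter (0.0392). The call of Krt13 ended without any single library other than knockout 1 (0.0529 to 0.0956), with no low-count filter (0.0726) and with limma-voom (0.135). Of 10 adipocyte genes, 1 rose and 4 fell, as also adjusted over the list alone (camera adjusted p = 0.137), Cidea, a lipid droplet gene, by 3.45 (SE 0.36), and Pparg (a nuclear receptor), Fabp4 and Acvr1c lower by 0.97, 1.89 and 3.31. The adipocyte genes lower numbered 2 without wild type 2, wild type 3 or knockout 3, and the call of Acvr1c ended without each of these (0.0587 to 0.0724). With both libraries numbered 1 left out, 8 of 12 were lower. Camera called the adipocyte list as lower without wild type 1 (0.00447), without both libraries numbered 1 (0.0103), with total counts (0.011) and with no low-count filter (0.016). The call of Pparg ended with total counts (0.0534). Of 8 erythrocyte genes, 6 rose and 1 fell, as also adjusted over the list alone, with the alpha-globin genes Hba-a2 and Hba-a1, whose reads are hard to part, higher by 4.59 (SE 0.43) and 4.62 (SE 0.53), Alas2, the haem synthesis gene, higher by 4.56 and Fech lower by 0.60 on the log2 scale. Camera placed the erythrocyte list higher (adjusted p = 0.0323), lost at adjusted p = 0.569 with an estimated correlation, at 0.0692 without knockout 1 and at 0.154 with total counts, where the call of Fech also ended (0.221). Only Clps (colipase) passed among 4 tested pancreatic acinar genes, lower by 3.66 (SE 0.73) on the log2 scale, and its call ended without knockout 2 (0.063). With 5 of these genes tested, 2 were lower without wild type 1 and 3 without knockout 1 or knockout 3. Camera then called the acinar list as lower (adjusted p = 0.0221, 0.033 and 0.0206), as it did without both libraries numbered 1 (0.016), where 2 were lower. With DESeq2 3 of 9 were lower.

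**Figure D3:**
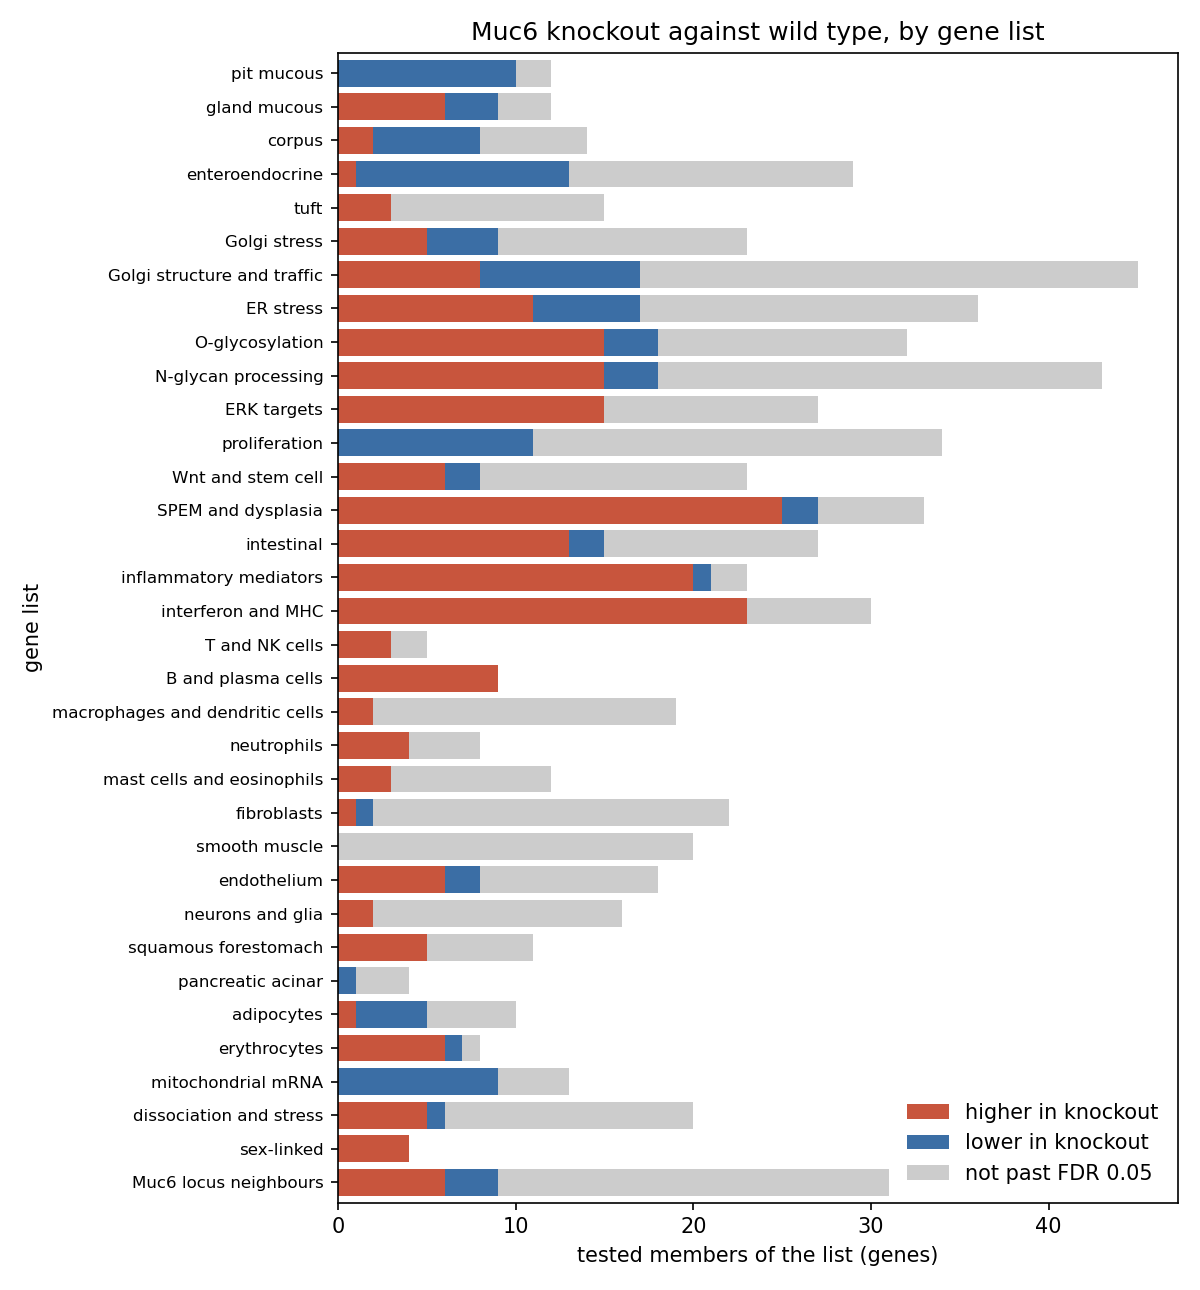
Number of tested genes in each list that were higher, lower or not past the threshold in the Muc6 knockout (bars start at 0 and stack). SPEM and dysplasia, interferon and inflammatory mediator lists hold the most genes higher, at 25, 23 and 20, and with total counts 10 proliferation genes were higher and 3 lower in place of the 11 lower shown.

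Signs of RNA quality and composition also differed between the genotypes. Of 13 mitochondrial mRNAs, 9 fell and none rose (10 adjusted over the list alone), with mt-Co2 lower by 1.96 (SE 0.19) on the log2 scale, from 14746 ± 3294 to 3791 ± 141 CPM, and mt-Nd1, mt-Cytb and mt-Nd6 lower by 1.12, 0.98 and 0.81. Mitochondrial mRNA took 8.37%, 13.01% and 11.81% of counts in wild type and 8.62%, 8.13% and 7.21% in the knockout. Camera placed this list lower (adjusted p = 7.16e-04), lost at adjusted p = 0.569 with an estimated correlation, and 5 members were lower without wild type 2, wild type 3, knockout 2 or knockout 3. With the GC trend removed, 3 were lower, the median was -0.13 and camera placed the list higher (adjusted p = 0.037), and the call of mt-Nd6 ended (0.501), as it did with total counts (0.0686), where 3 were lower. Among dissociation and stress genes, 5 of 20 rose and 1 fell (4 and 1 adjusted over the list alone), Hsph1, a heat shock gene, by 1.61 (SE 0.28), and Hspa1b and Hspa1a, near-identical heat shock genes, by 5.80 and 6.67, with 761 CPM of Hspa1b in knockout 3 against 102 and 131 in knockout 1 and 2. Atf3, an early response gene, fell by 1.15 on the log2 scale. The call of Hspa1b ended without wild type 1 (0.0518) or wild type 2 (0.053), that of Hspa1a without any 1 wild-type library (0.0581 to 0.0788), with no low-count filter (0.057) or with limma-voom (0.246). Without both libraries numbered 1 the calls of both ended (0.0746 and 0.0981), and with total counts that of Atf3 did (0.0587). The number higher was 1 without wild type 2 and 3 without wild type 3. Camera placed the stress list higher (adjusted p = 0.0342), lost at adjusted p = 0.569 with an estimated correlation, without wild type 2, wild type 3 or knockout 2 (0.0551 to 0.1), with total counts (0.16) and with the GC trend removed (0.988). With total counts 10 stress genes were nevertheless higher and none lower. The number higher was 8 with DESeq2 and 3 with limma-voom.

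All 4 tested sex-linked genes were higher in the knockout, also adjusted over the list alone, Ddx3y by 7.86 (SE 0.34), Eif2s3y by 7.68 (SE 0.79), Kdm5d by 3.90 (SE 0.17) and Uty by 2.34 (SE 0.15). Kdm5d and Uty, at 1.39 ± 0.13 and 4.56 ± 0.528 CPM in wild type, have close X-linked relatives with which they may share reads. Among genes near Muc6 on chromosome 7, 6 of 31 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.179). Tspan4, a tetraspanin gene, rose by 1.89 (SE 0.23), Phrf1, a ubiquitin ligase gene, by 0.97, and Muc5b, a gel-forming mucin gene, by 4.67 (SE 0.81), from 0.0925 ± 0.0855 to 2.52 ± 1.05 CPM, and Mob2 fell by 0.63 on the log2 scale. The neighbours higher numbered 11 without wild type 1, 13 without both libraries numbered 1 and 18 with total counts, where the call of Mob2 ended (adjusted p = 0.11), and camera called the list as lower with the GC trend removed (0.0473). With that trend removed, 5 neighbours were higher and 9 lower.

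The lists were also tested with fry, which compares no list with other genes. It called 19 lists for moving on balance one way and 28 for movement either way. It called 4 lists as higher that camera did not, Golgi stress (adjusted p = 0.0107), ER stress (0.0376), Wnt and stem cell (0.0282) and squamous forestomach (0.00905). For 7 lists called by camera, fry found no balance one way: proliferation (0.143), tuft (0.12), smooth muscle (0.366), macrophages and dendritic cells (0.188), endothelium (0.1), neurons and glia (0.246) and dissociation and stress (0.0749). For movement either way, tuft (0.0942), smooth muscle (0.368), macrophages and dendritic cells (0.108) and fibroblasts (0.175) did not pass.

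Changes across genes followed the GC content of the transcripts. Over 13988 genes, which are not independent replicates, the Spearman correlation of the log2 fold change with GC content was 0.342. In the 20% of genes with the lowest GC content, at a median of 41.1%, 181 were higher and 1084 lower, and in the 20% with the highest, at 57.8%, 831 were higher and 168 lower. With each library's GC trend removed these became 488 and 428, and 439 and 435, and 4797 genes changed in all, of which 3820 were among the 5386. The libraries' own correlations with GC content were -0.022, -0.48 and -0.315 in wild type 1, 2 and 3 and 0.253, 0.332 and 0.329 in knockout 1, 2 and 3.

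**Figure D4:**
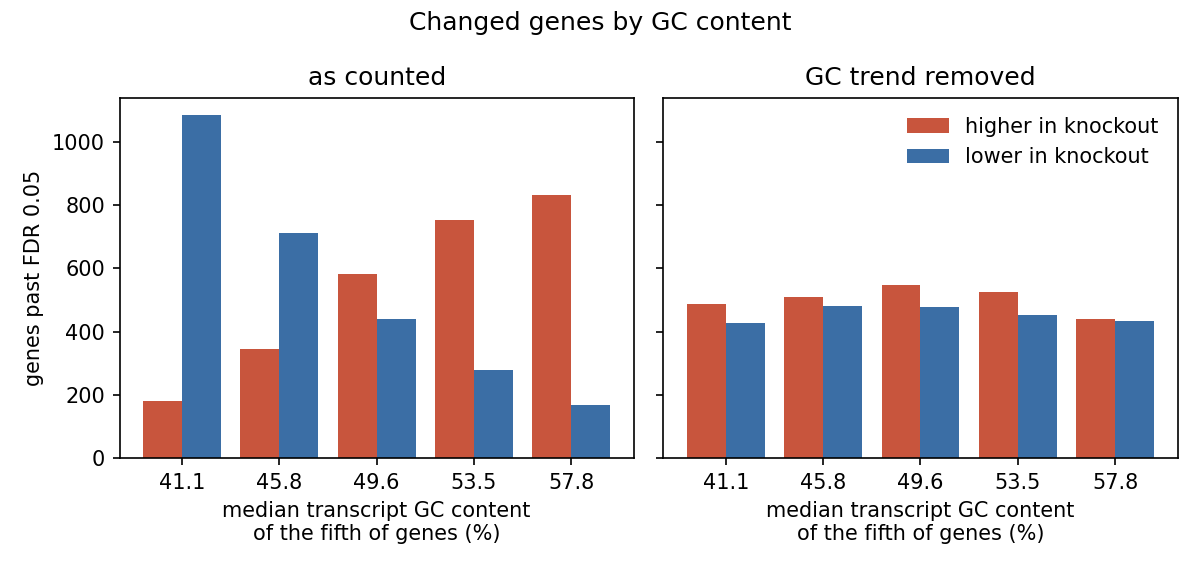
Number of genes higher or lower in the Muc6 knockout in each of 5 equal bins of genes by transcript GC content (median of the bin in percent), as counted and with each library's GC trend removed. As counted, the bin of lowest GC content held 181 higher and 1084 lower, and with the trend removed it held 488 and 428.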

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

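The settings with total counts, with the GC trend removed and without both libraries numbered 1 were chosen after the data were seen, and the rest were planned. Muc6 stayed lower and past the threshold in each setting run. Leave-one-out gave 3342 to 6009 genes changed, 1600 to 3045 higher and 1721 to 2964 lower against 5386, 2699 and 2687, and 19 to 24 lists against 22; the lowest counts came without wild type 2 and, for genes lower, without knockout 2. The cause was not tested beyond the loss of a library. The other planned settings gave 5069 to 5965 genes changed at 0.05 and 20 to 25 lists by camera, with 19 and 28 by fry. The main fit gave 6795 genes at the looser threshold of 0.1. It gave 2226 where a 2-fold change was also required, which sets a stricter threshold. Camera with an estimated correlation called 0 lists, where 3 had an unadjusted p under 0.05. Total counts gave 5730 higher, 1091 lower and 13 lists, since that setting leaves out the composition factor. The GC correction kept 3820 of the 5386 genes. With the replicate number as a block 5069 genes changed, 4682 of them shared. Whether the numbers pair the samples cannot be decided with 3 libraries of each genotype. Libraries of the same number correlated at 0.252 for number 1, 0.091 for number 2 and 0.191 for number 3. In each genotype 2 of 3 libraries correlated best with the library of their number, but wild type 3 correlated best with knockout 2 (0.275). The block called 12 of 20 smooth muscle genes as lower against 0, Casq2 among them (0.0182). It gave 10 endothelial, 6 mast cell and eosinophil, 5 tuft, 5 Golgi structure and 4 fibroblast genes higher against 6, 3, 3, 8 and 1, and 2 Golgi stress genes lower against 4. It moved the count of neuron and glia genes lower from 0 to 2, of squamous genes lower from 0 to 1, and of intestinal and endothelial genes lower from 2 to 1. It ended the calls of Fcgr3 (0.0685), Krt13 (0.056) and Lyve1 (0.0574) and the camera call of erythrocytes (0.0525). Of 135 named genes called, 23 lost the call in some left-out library, 21 in another planned setting and 21 in an added one, and 0 reversed. Depth limits genes at few counts most, where 1 count is worth about 0.05 CPM.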

Other observations

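The tests of chance, of sex, and of Muc13 and the Reg genes were chosen only after the result was seen. So were both tests of the proliferation genes. The comparisons of the enterocyte order with all tested genes, genes called higher and other lists were too. The GC test of all genes was chosen after the libraries' GC correlations were seen.

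Several genes outside the naming rule, chosen after their values were seen, add to the gastric picture. Muc5ac, the mucin of surface cells, fell by 2.91 (SE 0.55) on the log2 scale, from 6053 ± 280 to 804 ± 505 CPM, and Pgc, the pepsinogen C gene, fell by 2.99 (SE 0.78). Lgr5, a stem cell receptor gene, fell by 2.80 (SE 0.49) from 14.4 ± 4.36 to 2.07 ± 1.13 CPM, while the hormone gene Pyy rose by 1.61 (SE 0.45) and the somatostatin gene Sst fell by 3.24 (SE 0.83). A4gnt, which makes the sugar end typical of Muc6, was at 85.5 ± 16.4 CPM in wild type and 105 ± 64.6 CPM in the knockout (adjusted p = 0.648). The calls of Pgc and Sst ended without any 1 wild-type library or knockout 2 (adjusted p 0.0751 to 0.107 for each) and with no low-count filter (0.0834 and 0.0806), and that of Pyy without any single library other than knockout 1 (0.0612 to 0.102), with limma-voom (0.123) and with the GC trend removed (0.0636).

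Members of a list moved apart. In the ER stress list, Hspa5, the main ER chaperone gene, rose by 0.59 (SE 0.13), but Asns, Atf4 and Chac1, genes of the amino acid response, fell by 1.79 (SE 0.32), 1.08 (SE 0.22) and 4.56 (SE 1.11) on the log2 scale. In the O-glycosylation list, C1galt1 and its chaperone gene C1galt1c1, which extend the first sugar of mucins, fell by 0.76 (SE 0.12) and 1.03 (SE 0.16) while most others that changed rose. Among endothelial genes, Prox1 and Lyve1, both of lymphatic vessels, fell by 1.88 (SE 0.50) and 1.10 (SE 0.37). The call of C1galt1 ended with the GC trend removed (adjusted p = 0.0965), that of Chac1 without wild type 2 or any 1 knockout library (0.0531 to 0.0962), with no low-count filter (0.0675) and with limma-voom (0.234), that of Prox1 without wild type 2 (0.102) or knockout 2 (0.0779), and that of Lyve1 without any single library other than wild type 1 (0.0822 to 0.182), with upper-quartile factors (0.0533), total counts (0.161), limma-voom (0.0735) and the GC trend removed (0.0739). These genes were also chosen after their values were seen.

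The pattern weighed first is the 5386 genes changed. A GC trend as the whole cause is argued against by the correction, which kept 70.9% of the genes past the threshold with the same sign, while the rest may owe their call to the trend. Sex cannot be told apart from genotype, since 0 of the 3 wild-type libraries and all 3 knockout libraries expressed Y-linked genes. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and 1 split, the real one with 5386, reached that number (highest other 0); the other splits called 12 to 18 lists by camera with the preset correlation against 22. Loss of Muc6 and sex both stay open for genes other than Muc6 and the Y-linked genes. The libraries' correlations with GC content also parted by genotype, at -0.48 to -0.022 in wild type and 0.253 to 0.332 in the knockout. A difference in how the samples of the genotypes were dissected or prepared was not tested and stays open too.

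The pattern weighed second is the rise of intestinal genes. For Muc13, intestinal tissue of constant makeup as the whole source is argued against. The ratio of Cdh17 to Muc13 differed 35.5-fold among knockout libraries (0.022, 0.344 and 0.774). That ratio holds no Reg gene. Reg1, Reg3b and Reg3g did not follow Cdh17 either, at 142, 46.3 and 74.8 CPM in knockout 1 and 144, 43.7 and 38.9 CPM in knockout 3. Tissue of varying makeup, or as a part of the source, was not tested. For Cdh17, Sis and Mep1b intestinal tissue in the knockout samples may be the cause. Of 29 tested genes of an added enterocyte list, 22 (75.9%) had their knockout values in the order of Cdh17. This compares with 22.7% of all tested genes, 15.8% of genes called higher and 16.7% by chance. The order was not particular to intestinal genes. Median deviations from the mean of the 6 libraries also rose from knockout 1 to 3 in gastric lists. They were -1.03, -0.63 and -0.52 for pit mucous, -0.15, 0.48 and 0.87 for gland mucous and -1.58, -0.47 and -0.19 for enteroendocrine genes. Other lists fell, such as SPEM and dysplasia (1.31, 1 and 0.91). The order alone thus cannot name the tissue. Of the 29, 13 rose and 4 fell, and the order was that of Cdh17 in 11 that rose, 2 that fell and 9 that did not pass, so it was not limited to genes that rose. The calls of Cdh17 and Sis ended without any 1 wild-type library (adjusted p 0.0697 to 0.0717 and 0.0648 to 0.075), that of Cdh17 with no low-count filter (0.0521), and those of all 3 genes with limma-voom (0.232 to 0.481). Intestinal-type cells arising in the antrum predict the same order, so these stay open too.

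The last pattern weighed is the fall of proliferation genes, which turns with total counts. A GC trend is argued against, as 10 members were lower with it removed. For a lower share of epithelial cells, 23 added epithelial genes had a median of 0.121 (SD 0.657, lower quartile -0.098). That lies above the proliferation median of -0.204, whereas such a lower share predicts one below it. The test could not decide it, because it required the medians to differ by more than that SD. That SD is the spread of single genes and not the error of a median, so the test was weak. Of the 23 genes 6 were higher and 3 lower, with Krt8 at -0.50 and Epcam at 1.16. The composition scaling stays open, because with total counts 10 members were higher and 3 lower. Without both libraries numbered 1, a setting that kept this scaling, the median was 0.01, with 3 members higher and 11 lower. No test of a biological cause was run.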
